A study of Trichoderma reesei QM6a with 4 samples.

How the data were processed

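The files held 4 arrays of Trichoderma reesei, 2 of wild-type mycelium and 2 of AT01 mycelium, hybridised with Cy3-labelled RNA, per the labels' protocols. Images were read with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. The deposited intensity values, per the file headers, were background-subtracted processed signals on a linear scale, with flags for spots well above background, saturated or outlying. The deposited value table was on a log2 scale, judged from its values: each column followed the log2 processed signal of its own array (Pearson's r across probes 0.993 to 0.996), its columns had medians of 4.31, 4.31, 4.31 and 4.31, and it covered 28201 probes, 64.7% of those on the array. Equal quartiles across its columns mean that it was normalized between arrays. The method and the choice of probes are not given in the sources used here. All 4 columns shared a maximum of 18.5, as quantile normalization would give. The deposited table may therefore not be a check independent of the quantile normalization used below.

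The processed signal was log2-transformed and each array's 75th percentile over 43565 probes was subtracted. Control spots were left out, as were outlying spots (13, 24, 39 and 117), and no spot was saturated. Probes of a gene were averaged, mostly 5 distinct probes per gene. Of 9127 genes on the array, 8018 were tested, those with at least 1 probe well above background on both arrays of at least 1 strain; for 1714 of them, 21.4%, only 1 probe met this. Dim probes carry a lowest value that is nearly the same on every array before scaling, and after scaling lay at -3.88 and -3.82 on the wild-type arrays and -4.76 and -4.72 on the mutant arrays. A fall of a dim gene can therefore follow from the scaling alone, and a common lower limit of -3.82 was added for this reason. Where every array of a strain had none of a gene's probes well above background, the change is given as a bound. It sets the brighter strain's mean against the dim strain's mean of, per array, the higher of the lowest signal well above background and the probe's own.

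Array gene names carry a number, and 9070 of 9127 (99.4%) matched the number of a locus tag of the v2.0 assembly of strain QM6a. The files do not name the gene build behind the array, so the match rests on the shared number, and coordinates are left out. It was checked on the genes with ribosomal protein symbols, whose median brightness lay at the 98.9th percentile of all genes. The reference table gave 235 locus tags a symbol, 226 of them on the array and 214 tested, and gave no descriptions. Neighbouring genes were taken from the order of the table, with a break where positions started again.

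Strains were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Lists of at least 5 tested genes were compared with other genes by camera with a preset correlation of 0.01, and again with an estimated correlation. By fry each list was tested against no change instead of against other genes. The 28 lists chosen before the data were examined relied on gene descriptions, so 3 of them found any member by symbol: plant cell wall hydrolases, hydrophobins, and cell cycle and histones, the last with 1 gene, which was not called (-0.28). A further 13 lists were put together from the symbols after these had been seen and before the strains had been compared. The named genes follow a rule chosen beforehand, which asked for a gene description, so a symbol was used in its place. Named were the 12 largest rises and 12 largest falls among called genes with a symbol whose mutant arrays lay outside the wild-type range. Up to 2 rises and 2 falls per list were named too, and the rule was extended to the symbol lists. This gave 41 genes, since 11 genes with a symbol rose. Genes named by locus tag, and rpl16, pkac2, cel1a, cel7a, cel7b, cel12a, cel61b, gal7, lxr1, gld1, hh3, psa6, psa7 and bip1, were chosen after their values were seen.

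Data were simulated with the wild-type means of the 8018 genes and variances drawn from the distribution fitted to them, in 20 runs with 200 changed genes each. Recovered were 1.79% of changes of 0.5 on the log2 scale, 62.5% of changes of 1 and 97.1% of changes of 2. Of the calls, 4.58% were unchanged genes. The real comparison called 3558 genes, and the share of changed genes moves the cutoff of the adjusted p. The simulation also lacked the lower limit and the difference in array brightness. Its shares therefore do not give the recovery on the real arrays. A list shifted by -0.5 was called by camera with the preset correlation in 20 of 20 runs, and 0 of 180 unshifted lists was called. The simulated genes were independent of one another, so this does not test lists of correlated genes. For the ribosomal protein list the estimated correlation between genes was 0.61.

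Alternatives chosen beforehand were normexp background correction with an offset of 50, quantile normalization, median centring, no filter on dim genes, genes well above background on all arrays, the brightest probe per gene, the authors' deposited log2 table, a trended and robust prior variance, the replicate number as a block, and each array left out. The normexp setting used the median signal and median local background, because no mean signal column was used here. Its offset of 50 lies above the 75th percentile of the processed signal on every array, 20.9 to 41.5. Fold changes of dim genes therefore shrink in that setting by construction. Alternatives added after the data were seen were the common lower limit, the percentile over probes detected on all arrays, cyclic loess, averaging detected probes only, and genes with at least as many probes detected as not. Leaving out an array leaves 1 array in a strain, so a call lost that way may follow from the smaller number of arrays. All arrays lay on 1 slide and in 1 scan, so neither could act as a batch. Figures were drawn with matplotlib 3.10.9.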

Results

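Messenger RNA of Trichoderma reesei mycelium was measured on 4 one-colour Agilent arrays, 2 of the wild-type strain and 2 of AT01, a mutant described by the submitters as accumulating copper to a high degree. Both strains had grown for 5 days at 25 °C in YPD, a rich medium of yeast extract, peptone and glucose, with 1 mM CuSO4 added. The arrays were dim, and the mutant arrays were brighter than the wild-type arrays. The 75th percentile of the processed signal was 20.9 and 22.2 on the wild-type arrays and 41.5 and 39.6 on the mutant arrays, and 20919 and 20049 against 26590 and 26256 of the 43565 probes lay well above background. Over the 8018 genes tested, Pearson's r across genes was 0.987 between the wild-type arrays, 0.986 between the mutant arrays and 0.937 to 0.949 between the strains, where genes are not independent replicates. The labels do not say that the arrays of a strain came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays, 2 per strain, limits the precision of every value.

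The comparison asked which genes differ in mRNA level between AT01 and its wild type under copper. Among genes with a symbol, the small GTPase gene rho3 rose most, by 1.33 ± 0.12 on the log2 scale (SE, n = 2 arrays per strain), and mus8 rose by 0.74 ± 0.13. The hexose transporter gene hxt1, the G protein alpha subunit gene gna1 and xyr1, the transcriptional activator of cellulase and xylanase genes, fell, with log2 fold changes of -1.57 ± 0.12, -1.0 ± 0.13 and -0.77 ± 0.13. Adjusted p from limma with Benjamini-Hochberg adjustment was 0.00281 for rho3, 0.00887 for mus8, 0.00230 for hxt1, 0.00545 for gna1 and 0.00888 for xyr1. The signal of hxt1 was low: 1 of its 5 probes lay well above background on both wild-type arrays, and 1 of the 2 mutant arrays measured any of them. Its log2 fold change is thus set against a signal near background, and was -1.24 with a common lower limit for dim probes. The call of gna1 ended when its brightest probe alone was used, with a log2 fold change of -0.60 and an adjusted p from limma of 0.0960 after Benjamini-Hochberg adjustment. Of the 214 tested genes with a symbol, 11 rose and 91 fell. The counts were 11 and 74 with a common lower limit for dim probes and 18 and 29 with quantile normalization.

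**Figure D1:**
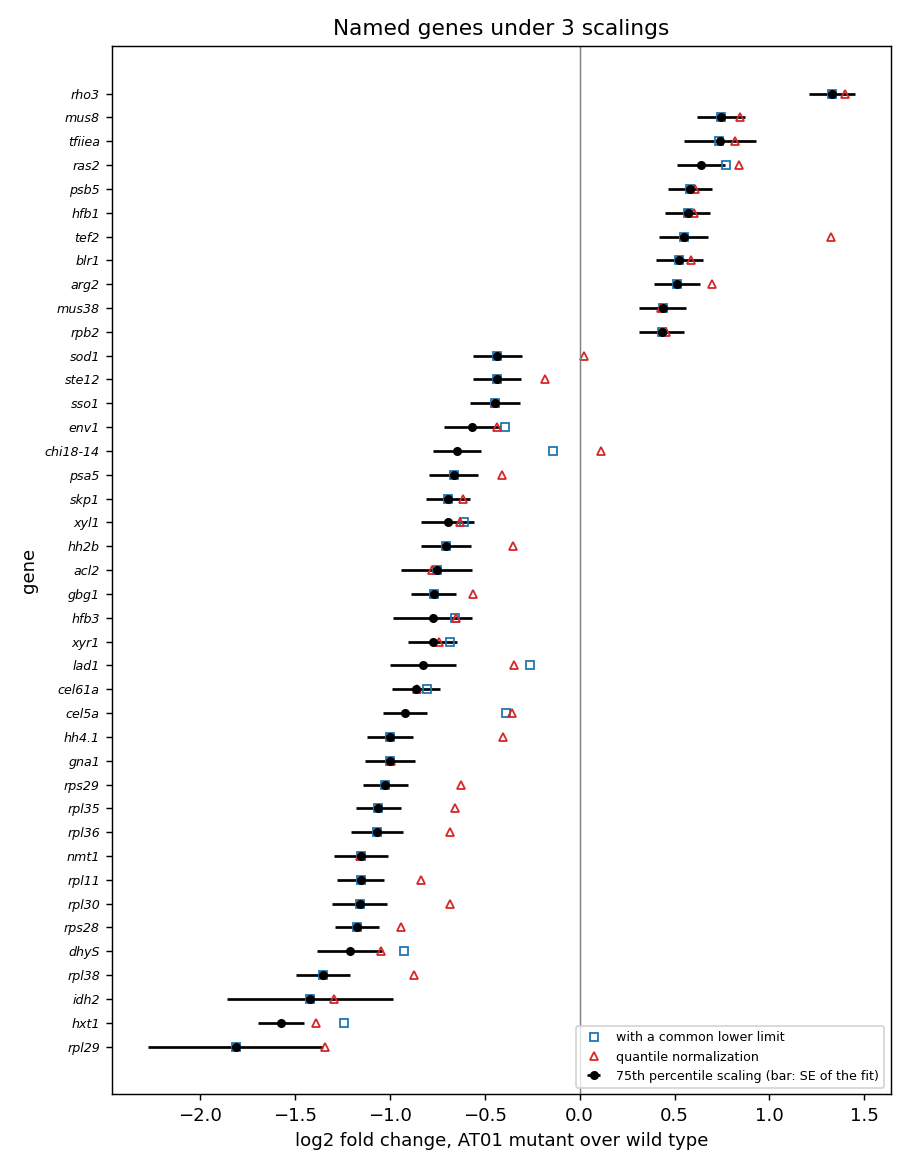
Log2 fold change of the AT01 mutant over the wild type (horizontal axis) for 41 named genes (vertical axis), with 2 arrays per strain. Black points with SE bars come from 75th percentile scaling, blue squares from the same scaling with a common lower limit, and red triangles from quantile normalization; rho3 lies at 1.33 with the first, and sod1 and chi18-14 cross 0 with quantile normalization.

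Besides rho3 and mus8, the genes with a symbol that rose were tfiiea at 0.74 ± 0.19, ras2, a Ras GTPase gene, at 0.64 ± 0.13, psb5, a proteasome beta subunit gene, at 0.58 ± 0.12, hfb1, which codes for a hydrophobin, at 0.57 ± 0.12, and tef2 at 0.55 ± 0.13. The blue light receptor gene blr1 followed at 0.52 ± 0.12, arg2 at 0.51 ± 0.12, mus38 at 0.44 ± 0.12 and rpb2, which codes for the second largest subunit of RNA polymerase II, at 0.43 ± 0.12. These 9 calls had adjusted p between 0.0129 for ras2 and 0.0331 for mus38 (limma, Benjamini-Hochberg). Each of the 9 was lost when at least 1 of the arrays was left out, but such a fit has 1 array in a strain and calls fewer genes in general. With an array left out, the log2 fold changes of the 9, whether called or not, lay between 0.38 and 1.0. With the brightest probe of each gene, hfb1 and blr1 turned to -0.38 and -0.35, not past the threshold. With normexp background correction tfiiea and ras2, both dim, turned to -0.07 and -0.08, also short of it. The normexp offset shrinks the fold changes of dim genes by construction. The call of mus38 ended with normexp (0.01), the brightest probe (0.15) and quantile normalization (0.43), and that of blr1 in the authors' deposited table (0.30). With the brightest probe the calls of ras2 (0.62), tef2 (0.71) and arg2 (0.59) ended too. The rise of tef2 was 1.33 with quantile normalization.

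Ribosomal protein genes were lower in the mutant. Of 42 tested, 36 fell, 0 rose, and the median log2 fold change was -0.77, against -0.23 over all genes tested. The list, put together from the gene symbols, lay below other genes by limma's camera test with a preset correlation (Benjamini-Hochberg adjusted p = 4.18e-08). That call was lost with an estimated correlation (adjusted p = 0.976 by limma's camera), a value shared by all 10 symbol lists tested. The estimate rests on 2 arrays per strain. By fry, which does not compare with other genes, the list was called (Benjamini-Hochberg adjusted p = 0.0414 by limma's fry). Examples were rpl38 at -1.35 ± 0.14, rps28 at -1.17 ± 0.12, rpl30 at -1.16 ± 0.14, rpl11 at -1.15 ± 0.12, rpl36 at -1.07 ± 0.14, rpl35 at -1.06 ± 0.12 and rps29 at -1.02 ± 0.12. The fold change of rpl29, -1.81 ± 0.46, rested on mutant arrays that read 4.17 and 2.64 on the scaled log2 scale, and ran from -1.05 to -2.58 with an array left out. Its call (limma's Benjamini-Hochberg adjusted p = 0.0256) ended without wild-type array 1 (-1.84) or wild-type array 2 (-1.78), with quantile normalization (-1.34) and with cyclic loess (-1.32). The size of the fall depended on the scaling. The median was -0.20 with 9 genes called lower and 1 higher, rpl16, after quantile normalization, and -0.27 with 11 lower and rpl16 higher after cyclic loess. With normexp background correction the camera call ended as well (median -0.23, limma's Benjamini-Hochberg adjusted p = 0.652).

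Most signalling genes were not called (16 of 21), and the others moved in both directions. Of 21 tested genes of G proteins and kinases, rho3 and ras2 rose, and gna1, gbg1 and the protein kinase A gene pkac2 fell, the last not with the common lower limit (-0.32, limma's Benjamini-Hochberg adjusted p = 0.0738), while the list as a whole did not stand apart from other genes (median -0.25, Benjamini-Hochberg adjusted p = 0.971 by limma's camera). The log2 fold change of gbg1 was -0.77 ± 0.12 (limma's Benjamini-Hochberg adjusted p = 0.00717). Of the 3 light response genes, blr1 rose and env1, which modulates light responses, fell by 0.57 ± 0.15 on the log2 scale, a call lost with a common lower limit for dim probes (-0.39, limma's Benjamini-Hochberg adjusted p = 0.0829). It was also lost without wild-type array 2 (-0.42), mutant array 1 (-0.63) or mutant array 2 (-0.50), and with quantile normalization (-0.44) and cyclic loess (-0.37). Of the 7 transcription regulators, xyr1 and ste12 fell (median of the list -0.23, Benjamini-Hochberg adjusted p = 0.958 by camera), and the list's median turned to 0.13 with quantile normalization. The log2 fold change of ste12 was -0.43 ± 0.13. Its call ended with quantile normalization (-0.18), with cyclic loess (-0.18), in the authors' table (-0.22) and when any 1 of the 4 arrays was left out (-0.35 to -0.52).

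Plant cell wall hydrolases, the only list fixed beforehand with at least 5 tested genes, had 10 tested genes, of which 6 fell (cel5a, cel61a, cel1a, cel7b, cel12a and cel7a) and 0 rose, and 6 fell when p was adjusted over the list alone. The list did not stand apart from other genes (median -0.48, Benjamini-Hochberg adjusted p = 0.136 by limma's camera, and adjusted p = 0.260 with an estimated correlation), whereas fry, which asks whether the genes of a list move one way on balance, gave a p of 0.00268. With a common lower limit for dim probes 2 of the 10 fell, cel5a and cel61a. With quantile normalization 1 fell, cel61a, and 1 rose, cel61b at 0.49, and with cyclic loess cel61a alone fell. The wider symbol list of cellulases and hemicellulose side enzymes had 8 falls among 13 genes, 3 with the common lower limit and 1 with quantile normalization or cyclic loess, and no call by camera (median -0.47, limma's Benjamini-Hochberg adjusted p = 0.238). Both lists named cel5a, an endoglucanase gene, at -0.92 ± 0.12, and cel61a, a polysaccharide monooxygenase gene, at -0.86 ± 0.13. The change of cel5a was -0.39 with the common lower limit and its call ended with quantile normalization (-0.36) and cyclic loess (-0.35). The change of cel61a turned to 0.48 with its brightest probe, short of the threshold, and its call ended in the authors' table (-0.30).

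Central metabolism gave scattered falls. Of 14 genes of glycolysis, the TCA cycle and acetate metabolism, 6 fell and 0 rose (median -0.27, Benjamini-Hochberg adjusted p = 0.448 by limma's camera), against 5 falls with the common lower limit, 2 with quantile normalization and 3 with cyclic loess. Among the 6 were idh2, an isocitrate dehydrogenase subunit gene, at -1.42 ± 0.44 and acl2, an ATP citrate lyase subunit gene, at -0.75 ± 0.19. The mutant arrays read 0.70 and -0.74 for idh2 on the scaled log2 scale, so its fold change ran from -0.70 to -2.14 with an array left out. Its call ended without wild-type array 1 (-1.36) and without wild-type array 2 (-1.48). With the common lower limit its fold change stayed at -1.42 while limma's Benjamini-Hochberg adjusted p rose to 0.0602. The call of idh2 ended as well with quantile normalization (-1.30), cyclic loess (-1.28), normexp (-0.81) and the percentile over detected probes (-1.30). At an unchanged -1.42 it also ended with a trended and robust prior variance and with the averaging of detected probes. The call of acl2 ended without either mutant array (-0.75 and -0.76) or without wild-type array 1 (-0.51). Of 9 genes of galactose and pentose use xyl1, lad1 and gal7 fell (median -0.12, limma's Benjamini-Hochberg adjusted p = 0.971 by camera, the median turning to 0.03 with the common lower limit and to 0.04 with quantile normalization), with xyl1, a xylose reductase gene, at -0.70 ± 0.14, a call lost without mutant array 1 (-0.58). With the common lower limit 1 of the 9 fell, xyl1, and the calls of lad1 (limma's Benjamini-Hochberg adjusted p = 0.295) and gal7 (-0.30, adjusted p = 0.125) ended. With quantile normalization xyl1 fell and lxr1 rose, at 0.98, and with cyclic loess xyl1 fell while lxr1 (1.02) and gld1 (0.44) rose. The gene lad1 was well above background on neither wild-type array and, with 1 of its 5 probes, on both mutant arrays. Detection thus runs against its call as lower, and no fold is given. Outside the lists, nmt1 fell by 1.15 ± 0.14 on the log2 scale and dhyS fell by 1.21 ± 0.17.

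The remaining symbol lists were not called by camera. Of 5 core histone genes 3 fell, hh3, hh4.1 at -1.0 ± 0.12 and hh2b at -0.70 ± 0.13 (median of the list -0.63, limma's Benjamini-Hochberg adjusted p = 0.238), and 0 fell with quantile normalization and 1, hh4.1, with cyclic loess. The call of hh2b also ended with normexp (-0.18), the brightest probe (-0.51) and in the authors' table (-0.40). Of 8 proteasome and ubiquitin genes, psb5 rose and skp1, psa5, psa6 and psa7 fell, with skp1, a subunit gene of SCF ubiquitin ligases, at -0.69 ± 0.12 and the proteasome alpha subunit gene psa5 at -0.66 ± 0.13 (median -0.42, limma's Benjamini-Hochberg adjusted p = 0.762). With quantile normalization or cyclic loess skp1 and psa6 alone fell, psa5 lying at -0.41 and -0.31. Of 12 secretory pathway genes 1 fell, the syntaxin gene sso1 at -0.45 ± 0.13, a call lost without wild-type array 1 (-0.34), wild-type array 2 (-0.55), mutant array 1 (-0.45) or mutant array 2 (-0.45), and with quantile normalization (-0.44), the brightest probe (-0.30) and the percentile over detected probes (-0.33). For the list, the median was 0.00, camera pointed up (limma's Benjamini-Hochberg adjusted p = 0.603), fry pointed down, and the median was 0.13 with quantile normalization, where bip1 rose (0.87) and none fell. Of 12 chitinase and N-acetylglucosaminidase genes 1 fell, chi18-14 at -0.65 ± 0.13 (median -0.27, limma's Benjamini-Hochberg adjusted p = 0.971), and both its change and the median turned positive with quantile normalization, at 0.11 and 0.12. Its call also ended with the common lower limit (-0.14), with cyclic loess (-0.02), in the authors' table (-0.21) and without mutant array 1 (-0.59). Of the 3 hydrophobin genes hfb1 rose and hfb3 fell, the latter at -0.77 ± 0.21, a call that ended with the common lower limit (-0.66, limma's Benjamini-Hochberg adjusted p = 0.0503), quantile normalization (-0.65) and cyclic loess (-0.62). It ended as well without wild-type array 1 (-0.51), mutant array 1 (-0.65) or mutant array 2 (-0.90). Of the oxidative stress enzymes, the superoxide dismutase gene sod1 was the 1 gene tested, at -0.43 ± 0.13, and lay at 0.02 with quantile normalization, past no threshold. Its call was lost when any 1 of the 4 arrays was left out (-0.33 to -0.53) and ended with cyclic loess (-0.02), the brightest probe (-0.32), normexp (0.06) and in the authors' table (-0.05). The list of copper handling genes recognised no symbol on the array, so that list was not tested and no gene is reported from it.

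Over all genes, 1122 rose and 2436 fell in AT01 at a Benjamini-Hochberg adjusted p under 0.05 in limma, and 287 rose and 258 fell at least 2-fold. That balance depended on the scaling: rises made up 31.5% of the changed genes, 48.4% with a common lower limit for dim probes (1123 rose, 1198 fell), 60.9% with quantile normalization (1136 rose, 729 fell), 60.2% with cyclic loess, 45.7% with the percentile over detected probes and 50.2% in the authors' deposited table. Falls stayed the larger part in other settings. Rises made up 25.2% with the brightest probe, 31.2% with genes well above background on all arrays and 15.3% with normexp. The median of all genes was -0.23, and -0.08 with the common lower limit and -0.01 with quantile normalization, so single falls are read against that shift. In 5 scalings alike, 978 genes rose and 637 fell, of which 286 and 199 had changed at least 2-fold with 75th percentile scaling. The number of changed genes was 2306 without mutant array 1 and 1661 without mutant array 2, against 3558 with all 4 arrays.

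**Figure D2:**
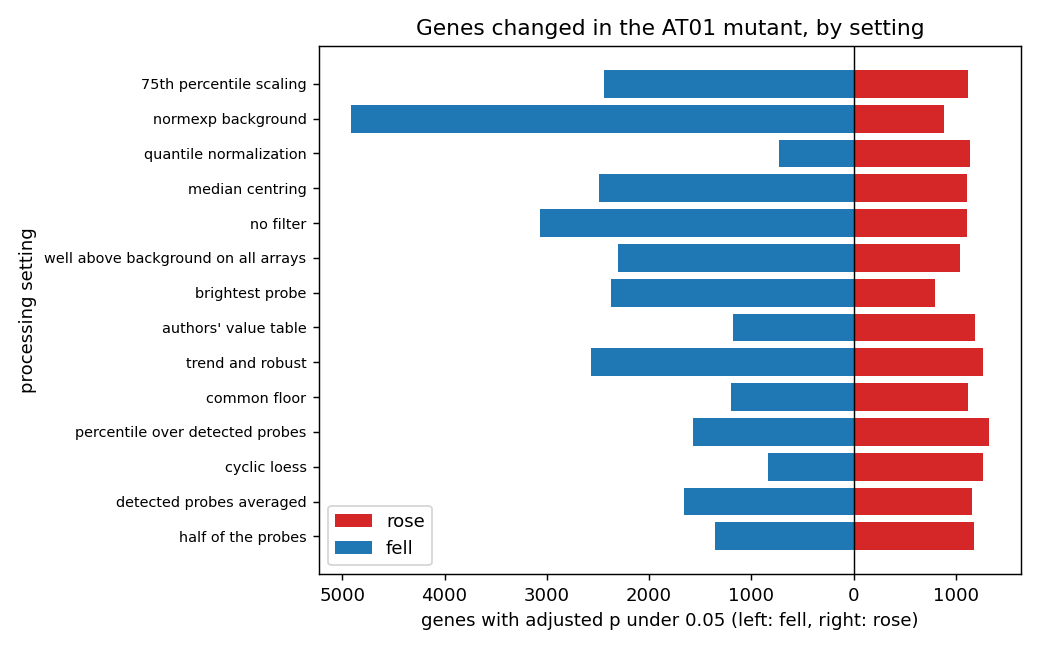
Number of genes with an adjusted p under 0.05 (horizontal axis, falls to the left of 0 and rises to the right) for each processing setting (vertical axis), with 2 arrays per strain. Rises vary less between settings than falls, which number 2436 with 75th percentile scaling, 4914 with normexp background correction and 729 with quantile normalization.

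Several of the largest falls lay near one another in the reference order, with loci that were not called in all scalings between them. The locus TRIREDRAFT_76215, chosen after its values were seen, fell by 4.90 ± 0.12 on the log2 scale (SE, n = 2 arrays per strain) and by 4.17 with the common lower limit, with 1 of its 5 probes well above background in the mutant. The size of its fall rests on that limit. A further 8 loci of a stretch of 35 fell in 5 scalings and at least 2-fold on the fitted scale, with at most 1 probe each well above background on both mutant arrays. The ends of the stretch were set after the values were seen, and joining falling loci across gaps of up to 16 loci instead gave 12 loci in a stretch of 54. Of the 9, 4 had no probe well above background in the mutant and so have only a bound: TRIREDRAFT_76218 fell at least 2.01-fold, TRIREDRAFT_120877 at least 1.70-fold, TRIREDRAFT_3055 at least 1.43-fold and TRIREDRAFT_120872 at least 1.15-fold. These bounds are for the average over probes. With the brightest probe alone TRIREDRAFT_3055 lay at -0.37, a smaller change than its bound, and TRIREDRAFT_76220 at -0.75, and both calls ended (limma's Benjamini-Hochberg adjusted p = 0.173 and 0.119).

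**Figure D3:**
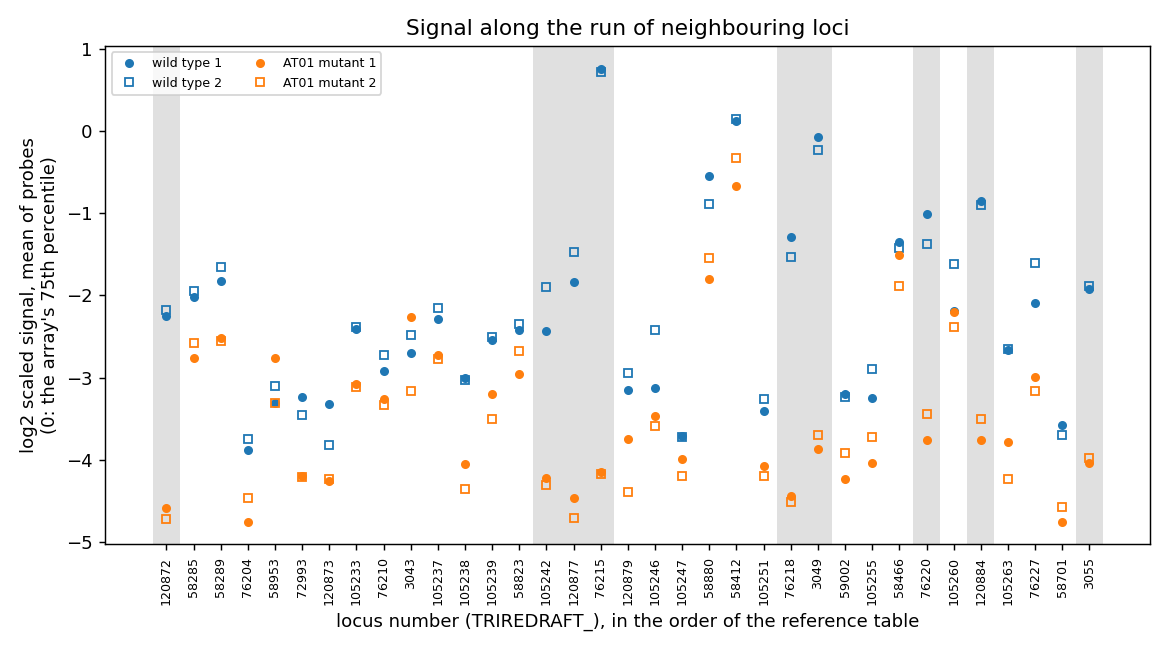
Log2 scaled signal, averaged over probes (vertical axis, 0 at the array's 75th percentile), of each array for 35 neighbouring loci in the order of the reference table (horizontal axis, no distances), with 2 arrays per strain and the 9 falling loci shaded. TRIREDRAFT_76215 lies at 0.76 and 0.72 on the wild-type arrays and at -4.15 and -4.18 on the mutant arrays, near the lower limit of those arrays.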

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

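The common lower limit, the percentile over detected probes, cyclic loess, the averaging of detected probes and the filter on the share of probes detected were chosen after the data were seen. The symbol lists were chosen after the symbols were seen and before the strains were compared. The slide and the scan were not run as blocks, because all arrays shared 1 slide and 1 scan. Signal over background is a limit, with 20049 to 26590 of 43565 probes well above background. Changed genes numbered 3558, against 5799 with normexp, 1865 with quantile normalization, 2321 with the common lower limit and 2106 with cyclic loess, and 1661 to 2576 with an array left out. Rises numbered 1122, and 559 to 912 with an array left out. Falls numbered 2436, against 4914 with normexp, 729 with quantile normalization, 1181 in the authors' table, 1198 with the common lower limit, 1568 with the percentile over detected probes, 839 with cyclic loess, 1356 among the 5243 genes with most probes detected, and 1102 to 1664 with an array left out. Genes changed at least 2-fold numbered 545, against 59 with normexp and 952 with the brightest probe. Rises of that size were 287, and 46 with normexp. Falls of that size were 258, against 13 with normexp, 121 with quantile normalization, 581 with the brightest probe, 142 in the authors' table, 144 with the common lower limit, 140 with the percentile over detected probes, 111 with cyclic loess and 153 among the same 5243 genes. The lower count among those 5243 genes follows in part from fewer genes tested. Of 1238 falls lost with the common lower limit, 1196 had a fold change nearer 0, which follows from its construction, and 42, idh2 among them, kept their fold change and lost the call through the adjusted p. With normexp the offset shrinks the fold changes of dim genes by construction, which bears on its small number of changes of at least 2-fold. Its part in the other normexp differences was not tested, nor was the cause for the remaining settings.

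With 2 arrays per strain, the replicate numbers share only a number: deviations of same-numbered arrays from their group means correlated at 0.01 across genes. As a block, the replicate number gave 1130 rises and 2643 falls, and it changed no call of a list or of the 65 genes followed. Of the lists chosen beforehand 0 were called by camera, and 1 by fry. Of the symbol lists 1 was called by camera, 0 with an estimated correlation and 2 by fry.

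List medians that changed sign, none of them called except where stated, were as follows. With quantile normalization chitinases lay at 0.12, the secretory pathway at 0.13, galactose and pentose use at 0.0443 and transcription regulators at 0.13. With cyclic loess these 4 lay at 0.00869, 0.17, 0.0264 and 0.0662. In the authors' table the secretory pathway lay at 0.0399, galactose and pentose use at 0.0645 and transcription regulators at 0.0697. With the common lower limit chitinases lay at 0.0180 and galactose and pentose use at 0.0294. The secretory pathway lay at 0.10 with normexp (called, Benjamini-Hochberg adjusted p = 0.00394 by limma's camera, 0.308 to 0.976 over its other settings), 0.0162 with the brightest probe, 0.12 with the percentile over detected probes, and between -0.11 and 0.0877 with an array left out. Galactose and pentose use lay at 0.00582 with genes above background on all arrays and between -0.295 and 0.0442 with an array left out.

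The 65 genes followed across 18 other settings were the 41 named genes and loci already called in 5 scalings. For those loci the common lower limit, quantile normalization, the percentile over detected probes and cyclic loess could not end the call. Of the 65, 33 kept direction and call in each setting that tested them, a share raised by that choice, and 8 changed sign in at least 1. These were tfiiea (-0.0724), ras2 (-0.0839) and sod1 (0.0601) with normexp, hfb1 (-0.38), blr1 (-0.35) and cel61a (0.48) with the brightest probe, chi18-14 (0.11) and sod1 (0.0214) with quantile normalization, and lad1 (0.00537) in the authors' table. The cause was not tested. Leaving out wild-type array 1, wild-type array 2, mutant array 1 or mutant array 2 ended 13, 11, 15 and 15 of the 65 calls.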

Other observations

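All tests on the neighbouring loci and on the balance of rises and falls were chosen after the result was seen, and those on ribosomal protein genes before their own result. The changes of greatest size were in genes without a symbol, chosen here after their values were seen. TRIREDRAFT_107298 rose by 3.70 ± 0.33 on the log2 scale (SE, n = 2 arrays per strain), with 5 of 5 probes well above background on both mutant arrays and 1 of 2 wild-type arrays measuring any of them. TRIREDRAFT_76481 rose by 2.42 ± 0.19, TRIREDRAFT_123014 by 2.22 ± 0.13, and TRIREDRAFT_79694, not well above background in the wild type, rose at least 1.99-fold. TRIREDRAFT_53722 fell by 2.35 ± 0.12 and TRIREDRAFT_46764 fell by 2.17 ± 0.13, each with all its probes detected in both strains. These 6 calls, picked among genes called in 5 scalings, held in each other setting tried that tested them. TRIREDRAFT_107003, at -2.80 ± 0.18, and TRIREDRAFT_34197, at -2.22 ± 0.12, lost theirs in the authors' deposited table (-0.22 and -0.33).

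The largest fall was that of TRIREDRAFT_76215, at -4.90 ± 0.12 (limma's Benjamini-Hochberg adjusted p = 0.000147), with 5 of 5 probes well above background in the wild type and 1 of 5 in the mutant, and -4.17 with the common lower limit. Its neighbours TRIREDRAFT_3049 and TRIREDRAFT_120884 fell by 3.63 ± 0.13 and 2.76 ± 0.14, each with 1 of 5 probes well above background in the mutant, and TRIREDRAFT_76218 fell at least 2.01-fold. With the common lower limit the log2 fold changes of TRIREDRAFT_3049 and TRIREDRAFT_120884 were -3.15 and -2.30. The size of these falls rests on the lower limit. In all, 9 loci in a stretch of 35 fell in 5 scalings with at most 1 probe well above background on both mutant arrays. By fitted log2 fold change, all 9 were among the 20 largest falls called in 5 scalings. That ranking includes fitted values for the 4 loci that have only a bound, so it rests on the lower limit as well. No rank is given with the common lower limit or with the bounds. With the brightest probe of each gene 2 of the 9 lost their call, TRIREDRAFT_76220 (from -2.42 to -0.75) and TRIREDRAFT_3055 (-0.37, where the average over probes has only a bound of at least 1.43-fold). With the 4 loci that have only a bound set at it, the median log2 fold change of the 9 was -2.10. That median is the value of TRIREDRAFT_105242, which had 0 probes well above background on both mutant arrays and lay at -1.37 with the common lower limit. It thus rests on the lower limit too.

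A pattern to weigh is this run. Scaling and the lower limit of dim probes were tested on loci chosen by 75th percentile scaling alone: its fullest window of 20 tested loci held 10 that fell at least 2-fold, 8 of them among the 9, and their median was -2.06 with the common lower limit, against -1.05 over all such falls, which argues against that limit as the whole cause. The values argue against chance placement too: a window of 20 tested loci held 8 of the 197 genes that fell in 5 scalings and at least 2-fold with 75th percentile scaling, and 0 of 10000 shuffled gene orders reached 8 (permutation p = 1e-04, the smallest they can give). Windows of 10 and 40 loci gave 0.0067 and 1e-04, and the fullest window of 20 for rises held 6 (permutation p = 0.087). Loss of the whole stretch from the AT01 genome was judged by loci with most of their probes well above background on both mutant arrays, and the answer depends on the boundary, which was drawn after the values were seen: 1 such locus lay among the 35, where the test could hardly find one, as the 26 other loci had at most 2 probes each well above background in the wild type, while joining falling loci across gaps of up to 6, 10 and 16 loci gave runs of 7, 11 and 12 loci with 2, 5 and 5 such loci, which argues against loss of those stretches as a whole. Of those 26 loci 19 had at least 1 probe well above background on both mutant arrays (29 probes, against 22 on both wild-type arrays), 4 of them with 0 on both wild-type arrays. The excess cannot be read as a gain, since more probes passed on the brighter mutant arrays everywhere (26590 and 26256, against 20919 and 20049). The scaled signal of most of the 26 was lower in the mutant. With 19 of them still above background there, loss of the stretch of 35 stays open only if those probes bind other RNA. A shared change in transcription or a smaller deletion may underlie the 9 falls, and neither was tested, nor was cross-hybridisation of the remaining bright probes.

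The lower level of ribosomal protein genes may reflect compression between dim and bright arrays, since these genes are among the brightest. The list's median of -0.77 lay at percentile 0 of 10000 random lists matched on brightness, whose central 95% ran from -0.47 to -0.07, and at percentile 0 of lists matched on brightness and gene length (-0.51 to -0.21), with a length for all 42 genes. Both comparisons go against brightness or length, as matched here, as the whole cause. The random lists were drawn gene by gene, so they lack the correlation between ribosomal protein genes, estimated at 0.61. Their percentiles thus do not allow for a shift that such genes share on an array. Brightness was matched in groups of ranks, within which the brightest genes can still differ. The median depended on the scaling, at -0.27 after cyclic loess and -0.20 with quantile normalization, but lay at percentile 0 of lists matched on brightness there too (central 95% from 0.01 to 0.44 and from 0.03 to 0.45). The camera call was lost with an estimated correlation (adjusted p = 0.976 by limma's camera, the value of all 10 symbol lists tested). A difference between the strains in growth or in growth stage at harvest remains an untested explanation.

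More genes fell than rose, 2436 against 1122. The lower limit of dim probes may account for part of this excess: with a common limit 1198 fell and 1123 rose. That limit raises mainly the dimmest values of the mutant arrays, so fewer falls follow in part from its construction. The excess stayed with the brightest probe of each gene (800 rose, 2372 fell) and with genes well above background on all arrays (1043 and 2304). It was wider with normexp (885 and 4914), so its source stays open. The mutant arrays were 1.88 times as bright as the wild-type arrays at the 75th percentile, with no overlap between the strains, so a difference in RNA or labelling yield cannot be told apart from the strain in these 4 arrays.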
